A study of Mus musculus with 2 samples.

How the data were processed

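The series holds 2 microarrays of 1 group, cultured fibroblastic reticular cells (FRCs) of mouse lymph node, which are named here replicate 1 and replicate 2 from the titles in the labels. Per the labels' protocols, lymph node stromal cells of untreated C57BL6/J mice aged 4 to 6 weeks were grown for 7 to 10 days in αMEM with 10% fetal calf serum, total RNA was isolated with a column kit, and single-stranded cDNA was fragmented and end-labelled with biotin. The source label calls the FRCs purified, and the step that purified them is not given in the sources used here. The labels do not say whether the replicates came from separate animals or cultures, so the spread between them may be technical in part.

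The deposited value table gives 1 intensity per probe set and array on a linear scale, made with RMA (robust multi-array average) per the submitters' processing notes, which give no version. RMA subtracts background, normalises the arrays run together by quantiles and summarises the probes of a probe set. It compresses differences at low signal and evens out differences in the whole distribution, so a change in total RNA per cell would not be seen. Which arrays were normalised together is not given in the sources used here. The intensities ran from 8.77 to 20232 on replicate 1 and from 8.20 to 20996 on replicate 2, with medians of 286.0 and 285.7. All further values are log2 intensities computed here from the deposited intensities. For arrays, depth has no counterpart in reads, and the number of arrays, 2, limits the precision.

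Of 24679 probe sets, 21354 had 1 gene in the platform's probe annotation, 1275 had several genes and 2050 had no row there. The last 2 kinds, 3325 probe sets, were left unnamed and out of all gene results, so genes that share a probe set, such as the Ccl21 genes, H2-K1 and H2-D1, were not analysed here. Gene identifiers were looked up in the RefSeq gene table of assembly GRCm38.p6, which held 21277 of the single-gene probe sets and not the other 77, and no symbol changed. The table was used for names only, and no coordinates are given because the sources used here name no genome build. Probe sets of 1 gene were averaged on the log2 scale, which gave 19751 named genes. In 188 of the 893 genes with more than 1 probe set, the probe sets fell on both sides of the background limit described next.

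The background limit of an array was the 95th percentile of its 1035 probe sets for olfactory receptors, which stand for genes without transcripts in a fibroblast. It was 7.15 on replicate 1 and 7.17 on replicate 2. A gene was counted as above the limit when it passed it on both arrays. A second limit, planned as an alternative, was the 95th percentile of 36 probe sets for genes restricted to tissues such as liver, retina, testis and pancreas, and was 8.08 and 8.18. Both counts are given, because 14 of the 35 measured tissue-restricted genes (40%) passed the olfactory receptor limit themselves. No level of a gene was set against the level of another gene, since probes differ in how strongly they bind.

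With 1 group there was no comparison of conditions, so no significance test was run and no p-value is given. The tests of explanations in the closing section set list medians, shares or a fitted trend against stated predictions. Differences between the replicates are replicate 2 minus replicate 1 on the log2 scale, over the 13577 genes whose mean level lay above the mean limit of 7.16. Where 1 array lay at or below its limit, the fold is given as "at least", with that array set to its limit. For a gene list with at least 5 such members, the median difference was placed among the medians of 10000 random lists of equal size matched on level in 20 bins, as a description of these 2 arrays. Medians outside the central 95% of the random lists were counted.

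The gene lists (39), the limits, the alternatives and the rule for named genes were fixed before the data were examined. Of 593 list genes, 534 were measured by a probe set of their own. The rule named a set of marker genes in each list whatever their value, the members on the smaller side of the limit where these were 5 or fewer, and the 10 genes with the largest difference in each direction. A further 5 lists, used only for tests of explanations, were written after the data were seen. Genes outside the rule are marked in the text as chosen after their values were seen. The alternatives were other percentiles and other gene sets for the limit, 1 array instead of both, the highest or lowest probe set of a gene, each array left out, quantile normalisation, removal of a loess trend with span 0.3, no filter or a stricter filter on level, and a 1.5-fold difference. Counts of 2-fold differences with arrays below a limit set to it were added after the data were seen.

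The counting of differences was tested on simulated data with the 13577 genes and normal noise of the size seen in the olfactory receptor probe sets. It recovered 98 of 100 planted 2.5-fold differences, 100 of 100 planted 4-fold differences, and called 0 of 13377 unchanged genes. The measured differences of the 13577 genes were wider, with an SD of 0.293 against 0.153 in the olfactory receptor probe sets. The simulated counts therefore check the counting and give no error rate for the measured genes. For the list shift, on the same 13577 genes, 50 of 50 random lists of 15 genes moved by 0.2 fell outside the central 95%, against 1 of 50 lists left as they were. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.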

Results

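Gene expression was measured by microarray in culture-expanded FRCs, the fibroblasts that build the reticular network of lymph nodes and guide lymphocytes through it. The series has 1 group with 2 replicate arrays and no second condition to compare with, so the values describe the transcriptome of the cultured cells and how far the replicates differed. Levels are log2 intensities, given as mean ± SD over n = 2 arrays. Of 19751 named genes, 13300 (67.3%) lay above the olfactory receptor limit on both arrays, 504 on 1 array and 5947 on neither. Above the stricter tissue-restricted limit lay 9856 genes (49.9%). Where few members of a list passed the stricter limit they are named, and of these H2-DMa, Deaf1, Egfl7, Cd53, Krt19, Tnnt3, Des, Apoa2 and Oxt were chosen after their values were seen.

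Most genes of the surface markers by which FRCs are recognised gave signal. RNA was measured and not protein, and the series holds no other cell type for comparison. Podoplanin (Pdpn), the glycoprotein used to sort FRCs, had a level of 12.67 ± 0.10, and the platelet-derived growth factor receptors Pdgfra and Pdgfrb had 11.89 ± 0.07 and 12.96 ± 0.22. Thy1 was at 12.48 ± 0.29, the adhesion molecule Vcam1 at 11.79 ± 0.09 and the lymphotoxin receptor Ltbr at 10.24 ± 0.09. Of 12 measured identity genes, 10 lay above the olfactory receptor limit and 9 above the tissue-restricted limit. Fap (5.96 ± 0.01) and Bst1 (6.56 ± 0.14) lay below both limits.

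The list of lymphoid chemokines and survival factors was mixed, and it also holds factors for myeloid cells such as Csf1. Above the limit lay 11 of 13, but only 6 passed the tissue-restricted limit, among them Cxcl12 (9.79 ± 0.24) and the myeloid growth factor Csf1 (13.65 ± 0.15). Ccl19, the ligand of the T cell homing receptor CCR7, was at 8.01 ± 0.23, averaged over 4 probe sets. The lymphocyte survival cytokine Il7 was at 8.20 ± 0.65, Il33 at 7.77 ± 0.47 and the B cell survival factor Tnfsf13b at 7.94 ± 0.12. These 4 genes passed the first limit on both arrays, and Ccl19, Il7 and Il33 passed the second on replicate 1 only and Tnfsf13b on neither. The B cell chemokine Cxcl13 (5.93 ± 0.04) and Il15 were below the limit.

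Matrix and contractile genes gave signal almost throughout. Of 27 matrix genes, 26 lay above the limit and 25 above the tissue-restricted limit, with Col1a1 at 12.77 ± 0.37, Col3a1 at 10.68 ± 0.88, Col6a1 at 10.09 ± 0.99, Fn1 at 13.83 ± 0.05, Dcn at 11.02 ± 0.25 and Postn at 12.78 ± 0.65. The exception was Lum. All 15 measured matrix turnover genes passed the limit and 12 the stricter one, with Mmp2 at 12.44 ± 0.25, Mmp14 at 12.67 ± 0.06, Timp1 at 13.85 ± 0.01 and Mmp3 at 7.55 ± 0.23. All 16 contractile genes passed both limits, including smooth muscle actin Acta2 (14.04 ± 0.03), Tagln (13.30 ± 0.10), Cnn1 (12.58 ± 0.26) and vimentin, Vim (14.07 ± 0.02).

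Among 22 immunoregulatory genes, 16 were above the limit and 14 above the stricter one. The prostaglandin synthesis genes Ptgs2 and Ptges had levels of 13.81 ± 0.21 and 11.06 ± 0.33, Tgfb1 11.28 ± 0.04, Il6 11.46 ± 0.89, galectin-1 (Lgals1) 13.94 ± 0.03, Hgf 10.12 ± 0.81, Cd274, which encodes PD-L1, 8.59 ± 0.01, and Tnfaip6 8.40 ± 0.02. Nos2, the inducible nitric oxide synthase, was at the limit (7.15 ± 0.00, above it on 1 array), and Ido1 was below it (6.43 ± 0.02). Of 20 inflammatory cytokines and chemokines, 11 passed the limit and 8 the stricter one, with Ccl2 at 12.01 ± 0.16, Ccl7 at 11.68 ± 0.13, Cxcl1 at 9.50 ± 0.09 and Cxcl10 at 8.56 ± 0.28. Il1b (6.40 ± 0.01) and Tnf (6.55 ± 0.04) were below it.

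Sensing and presentation genes were above the limit in part. Of 26 innate and cytokine receptor genes, 21 passed the limit and 18 the stricter one. Tlr3 was at 8.74 ± 0.16, Tlr4 at 8.97 ± 0.37, Tlr2 at 8.11 ± 0.03, Cd14 at 7.87 ± 0.22, Tnfrsf1a at 11.39 ± 0.16 and Ifngr1 at 11.27 ± 0.18, while Tlr1, Tlr6, Tlr7, Tlr8 and Nod2 did not pass on both arrays. For MHC class I, 8 of 9 genes passed and 6 the stricter limit, with B2m at 13.47 ± 0.08 and Tap1 at 9.05 ± 0.00, and Psmb8 below. For MHC class II and costimulation, 6 of 11 passed and 3 the stricter limit, which were H2-DMa, Cd80 (10.07 ± 0.07) and Cd40 (8.71 ± 0.57). The class II regulator Ciita was at 7.21 ± 0.04 and H2-Ab1 at 8.07 ± 0.07, and H2-Aa (5.95 ± 0.09), Cd74 (6.99 ± 0.05), Ctss, Cd86 and Icosl were below the limit. Of 11 genes studied as peripheral tissue antigens or their regulators, 7 passed and 2 the stricter limit, Aire (8.16 ± 0.04) and Deaf1. Aire passed the stricter limit only narrowly on replicate 2 (8.185 against 8.179). Mlana (7.69 ± 0.05) and Ppy (8.02 ± 0.06) passed only the first, Ins2 (7.16 ± 0.07) passed on 1 array, and Tyr (5.65 ± 0.10), Gpa33 (6.91 ± 0.03) and Fabp2 were below.

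In the complement list, 3 of 7 genes passed (C1s1, C1qtnf6 and Serping1, the last at 9.01 ± 1.67). Only C1qtnf6, a C1q and TNF related gene rather than a complement component, passed the stricter limit. C4b (7.10 ± 0.01), C1ra, C2 and Cfb were below. Of 15 interferon-stimulated genes, 10 passed and 8 the stricter limit. Irf7 was at 8.39 ± 0.26, Ifit1 at 7.19 ± 0.62 and above the limit on 1 array like Ifit3, and Rsad2, Mx1 and Mx2 were below.

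Genes of proliferation, stress and metabolism were above the limit with few exceptions. All 23 cell cycle genes passed and 21 the stricter limit, with Mki67 at 9.98 ± 0.76, Top2a at 10.24 ± 0.60 and Mcm2 at 10.18 ± 0.19. Of the 9 cell cycle inhibitors and p53 targets, 9 passed and 8 the stricter limit (Cdkn2a 9.13 ± 0.03, Mdm2 12.72 ± 0.15). The 17 immediate early genes (Fos 8.52 ± 0.30, Jun 11.44 ± 0.12, Egr1 10.74 ± 0.02, Atf3 9.19 ± 0.48), 13 cholesterol synthesis genes (Hmgcs1 9.91 ± 0.31), 15 unfolded protein and amino acid stress genes (Hspa5 12.89 ± 0.20, Ddit3 10.15 ± 0.17, Atf4 9.81 ± 0.03, Asns 12.37 ± 0.27), 9 heat shock genes (Hspa1a 9.57 ± 0.30, Hspb1 12.75 ± 0.05) and 9 housekeeping genes (Actb 14.21 ± 0.01, Tbp 10.34 ± 0.04, Hprt 11.57 ± 0.00, Eef1a1 14.15 ± 0.01) passed both limits in full. Of 14 hypoxia and glycolysis genes, 13 passed and 12 the stricter limit, with Slc2a1 at 12.89 ± 0.36, Ldha at 13.73 ± 0.06 and Vegfa at 12.34 ± 0.15, and Car9 passed on 1 array.

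Among 20 growth factors and morphogens, 18 passed and 17 the stricter limit, with Fgf7 at 12.82 ± 0.01, Wnt5a at 11.61 ± 0.17, the BMP antagonist Grem1 at 12.85 ± 0.16, Ccn2 at 14.09 ± 0.02, Vegfc at 9.78 ± 0.34 and Igf1 at 9.56 ± 1.68. Fgf10 and Rspo3 passed on 1 array each. Of 35 mesenchymal and positional transcription factors, 32 passed and 22 the stricter limit. Prrx1 was at 12.76 ± 0.01, Twist1 at 9.52 ± 0.14, Hoxc6 at 10.18 ± 0.02, Hoxa9 at 8.42 ± 0.02, and Nkx2-3 and Tlx1, known from spleen development, at 8.18 ± 0.20 and 7.48 ± 0.08. Tcf21 (7.04 ± 0.14), Meox1 and Meox2 did not pass on both arrays. Of 13 progenitor and lineage genes, 10 passed and 8 the stricter limit, with Eng at 12.07 ± 0.13, Cd44 at 12.59 ± 0.11 and Sox9 at 11.25 ± 0.31, and Lepr (5.60 ± 0.13), Sp7 and Ibsp below.

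**Figure D1:**
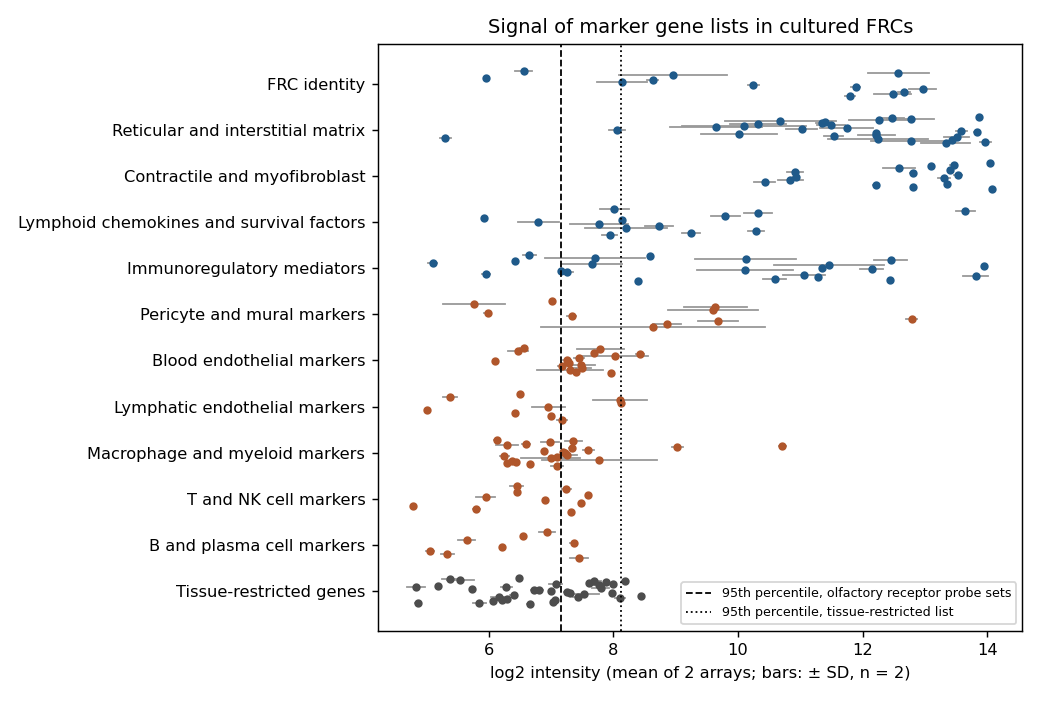
Log2 intensity of the genes of 12 marker lists on the x axis, 1 point per gene at the mean of 2 arrays with bars of ± SD (n = 2), lists on the y axis, and the mean olfactory receptor limit (7.16) and tissue-restricted limit (8.13) as vertical lines. All 16 contractile genes lie to the right of both lines, and no T and NK or B cell marker lies to the right of the second.

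Markers of the other cells that a lymph node stromal culture could hold lay mostly below the stricter limit. Of 9 lymphatic endothelial markers, 2 passed the first limit (Flt4 8.10 ± 0.43 and Itga2b) and 0 the second, with Prox1 at 6.42 ± 0.03, Lyve1 at 6.95 ± 0.26 and Mmrn1 at 5.0 ± 0.03. Of 16 blood endothelial markers, 11 passed the first and 1 the second (Egfl7). Cdh5 was at 7.79 ± 0.37, Kdr at 7.29 ± 0.03 and Emcn at 8.02 ± 0.54, Pecam1 (7.18 ± 0.06) and Tek passed on 1 array, and Chst4, Glycam1 and Ackr1 were below. Among 22 macrophage and myeloid markers, 8 passed and 2 the second limit, Cd68 (9.03 ± 0.09) and Cd53. The pan-leukocyte gene Ptprc was at 6.44 ± 0.04, Itgam at 6.25 ± 0.07, Csf1r at 7.60 ± 0.09, Tyrobp at 7.10 ± 0.10 and Lyz2 at 7.77 ± 0.92. For T and NK cells, 4 of 10 passed (Cd3e 7.59 ± 0.02, Cd8a 7.48 ± 0.01, Zap70 and Cd247) and 0 the second, with Cd4 at 6.91 ± 0.01 and Ncr1 at 5.80 ± 0.06. For B and plasma cells, 2 of 8 passed (Pax5 7.45 ± 0.14 and Cd79b) and 0 the second, with Ms4a1 at 5.34 ± 0.11. The share of tissue-restricted genes that passed the first limit, 40%, applies beside these counts, with Alb at 5.54 ± 0.21, Apoa1 at 7.69 ± 0.10, Prm1 at 7.43 ± 0.07 and Myh6 at 7.30 ± 0.05, and 2 of those 35 genes passed the second limit, Apoa2 and Oxt.

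Pericyte and mural markers, which cultured fibroblasts can share, passed in 7 of 10 cases and in 5 above the stricter limit, with Mcam at 12.78 ± 0.08, Cspg4 at 9.64 ± 0.50, Notch3 at 8.86 ± 0.23 and Rgs5 at 8.64 ± 1.80, and Abcc9, Angpt1 and Higd1b below. Adipocyte markers passed in 7 of 9 cases and in 3 above the stricter limit, with Pparg at 9.51 ± 0.68, Fabp4 at 7.85 ± 0.72, Plin1 at 7.79 ± 0.11, and Adipoq (5.49 ± 0.04) and Lep below. Of 6 follicular dendritic cell markers, 3 passed (Mfge8, Sox9 and Coch) and 2 the stricter limit, while Cr2 (5.69 ± 0.01), Fcer2a (6.19 ± 0.09) and Fcgr2b (6.15 ± 0.11) were below. Epithelial markers passed in 7 of 10 cases and in 2 above the stricter limit, Krt8 (8.47 ± 0.04) and Krt19, with Krt14 at 7.47 ± 0.14, Krt18 at 7.85 ± 0.02, Cdh1 (7.15 ± 0.14) above on 1 array, and Epcam (6.65 ± 0.01) and Esrp1 below. Schwann and neural markers passed in 4 of 6 cases (Sox10 8.04 ± 0.05, Mbp, L1cam and Ncam1) and in 1, Ncam1, above the stricter limit, and S100b and Gfap were below. Skeletal muscle markers passed in 7 of 10 cases and in 3 above the stricter limit (Acta1 11.24 ± 0.09, Tnnt3 and Des), with Ckm at 8.11 ± 0.01, Myod1 at 7.70 ± 0.19, and Myh1, Myh4 and Myf5 below. Of 5 mesothelial markers, 4 passed (Msln 7.96 ± 0.09, Upk3b 7.54 ± 0.04, Wt1 and Upk1b) and 1 the stricter limit, Upk1b, with Lrrn4 above on 1 array. The 1 erythroid marker measured, Alas2 (6.93 ± 0.07), was below the limit. Of 4 sex-linked genes, the Y-linked Eif2s3y (10.34 ± 0.00), Kdm5d (9.19 ± 0.06) and Uty (9.53 ± 0.11) passed both limits on both arrays, and Xist (5.54 ± 0.01) passed neither.

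The replicates were then set against each other. Matrix genes were higher and cell cycle genes lower on the replicate 2 array, and a small set of genes differed by several fold. The largest differences in favour of replicate 2 were those of Prelp (11.4-fold, log2 8.16 and 11.67 on replicates 1 and 2), the gap junction gene Gjb2 (10.6-fold), Cygb (9.96-fold), Fmod (8.99-fold), Aoc3 (6.93-fold), Ccn5 (6.75-fold), Tmem119 (6.41-fold) and Cmklr1 (6.28-fold). Ogn was at least 4.93-fold and Epha3 at least 4.35-fold higher there. Prelp, Fmod and Ogn encode small leucine-rich proteoglycans of the matrix. In favour of replicate 1, the cytokine Il1a differed most (at least 8.58-fold, log2 10.27 and 5.74), followed by the neutrophil-attracting chemokine Ppbp (5.27-fold), Kcnk10 (4.56-fold), Fam110c (4.22-fold), the related chemokine Cxcl5 (4.02-fold), Lce1h (3.55-fold), Cck (3.26-fold) and Gfra2 (3.25-fold). Gpr149 was at least 2.82-fold and Prl8a9 at least 2.18-fold higher there. Each of these differences rests on 1 array per side and has no replicate check. In 13 of the 20 genes the lower array lay below the tissue-restricted limit, and against that limit the folds are smaller lower bounds. Examples for replicate 2 were at least 6.89-fold for Gjb2, 4.89-fold for Fmod, 4.39-fold for Aoc3 and 3.98-fold for Cmklr1. Examples for replicate 1 were at least 4.33-fold for Kcnk10, 4.27-fold for Il1a, 3.29-fold for Ppbp and 2.24-fold for Cxcl5. The bounds were under 2-fold for Gpr149 (1.40) and Prl8a9 (1.08).

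Across the 13577 genes above the mean limit, Pearson's r between the arrays was 0.982 and Spearman's rho 0.980, and across all named genes they were 0.992 and 0.992. These are correlations across genes, which are not independent replicates. The median SD of a gene was 0.078 and the 95th percentile 0.40, and the median difference was 0.0046. A difference of at least 2-fold was found in 192 genes (1.41%), 142 higher in replicate 2 and 50 in replicate 1, counted on the measured values. With arrays below a limit set to it, a choice made after seeing the data, 181 genes (137 and 44) differed 2-fold for the olfactory receptor limit and 142 genes (112 and 30) for the tissue-restricted limit. At 1.5-fold the counts were 648 genes, 389 and 259. Of 1035 olfactory receptor probe sets, 0 differed 2-fold and 3 differed 1.5-fold, which describes background signal, where RMA compresses differences, and gives no noise estimate for genes above the limit.

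**Figure D2:**
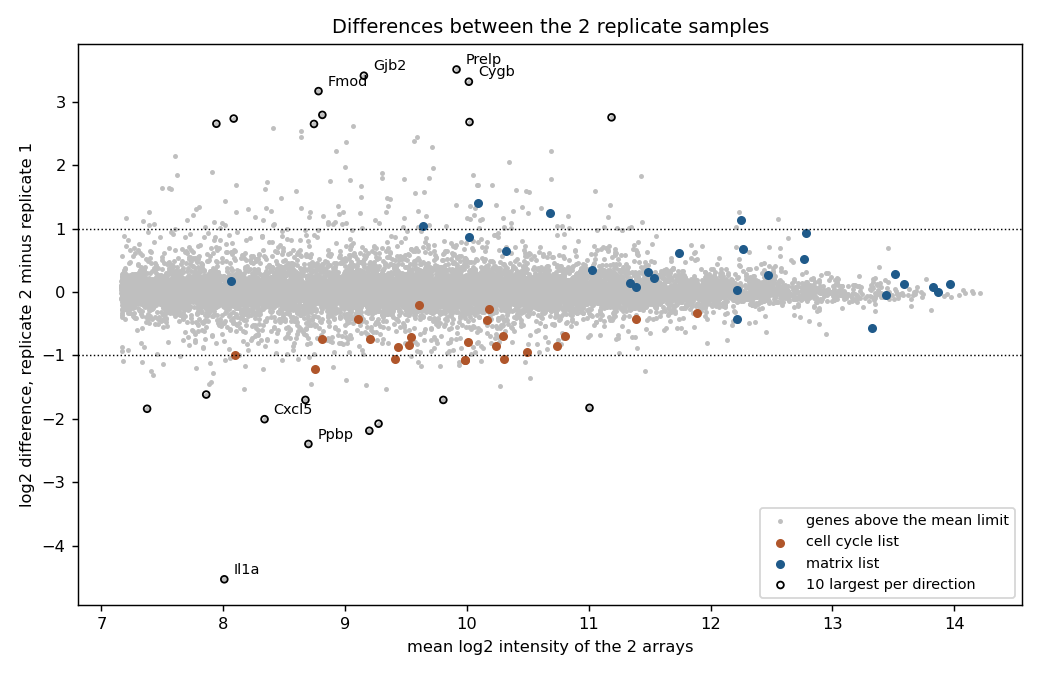
Difference between the arrays (log2, replicate 2 minus replicate 1) on the y axis against the mean log2 intensity on the x axis for 13577 genes, with cell cycle genes in orange, matrix genes in blue, the 10 largest differences per direction circled, and dotted lines at 2-fold. All 23 cell cycle genes lie below 0 and 22 of 26 matrix genes above it.

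Whole lists moved too. Of 30 lists with enough members, 12 had a median difference outside the central 95% of matched random lists, where 1.5 would be expected by chance if the genes within a list varied independently of each other. Genes that are regulated together do not, so the expected number is too low for such lists. Cell cycle genes had a median difference of -0.79, with 23 of 23 lower on replicate 2, 5 of them at least 2-fold, among them Mki67 (2.10-fold), and Top2a differed 1.80-fold. The central 95% of random lists of that size, called the random range below, lay between -0.08 and 0.10. Hypoxia and glycolysis genes had a median of -0.26, with 12 of 13 lower on replicate 2, such as Slc2a1 (1.42-fold). The lymphoid factors had -0.18, with 7 of 11 lower on replicate 2, such as Il7 (1.89-fold), although the median level of these 11 genes was 8.66 on replicate 1 and 8.90 on replicate 2. Blood endothelial markers had -0.09, with 9 of 13 lower.

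Higher on replicate 2 were the pericyte and mural markers (median 0.46, 6 of 7 genes), matrix turnover genes (0.35, 12 of 15, Mmp2 1.27-fold), matrix genes (0.27, 22 of 26, Col6a1 2.64-fold and Col3a1 2.38-fold), adipocyte markers (0.22, 5 of 7), cholesterol synthesis genes (0.20, 9 of 13), interferon-stimulated genes (0.15, 9 of 12), FRC identity genes (0.13, 9 of 10) and innate and cytokine receptors (0.12, 16 of 22). Contractile genes (-0.01) and housekeeping genes (-0.0042) were inside the range of random lists, as were the other 16 lists. Under other filters or probe set choices the lymphoid, interferon, adipocyte and blood endothelial medians came to lie inside the random range, and with a stricter level filter the matrix turnover median was 0.66.

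**Figure D3:**
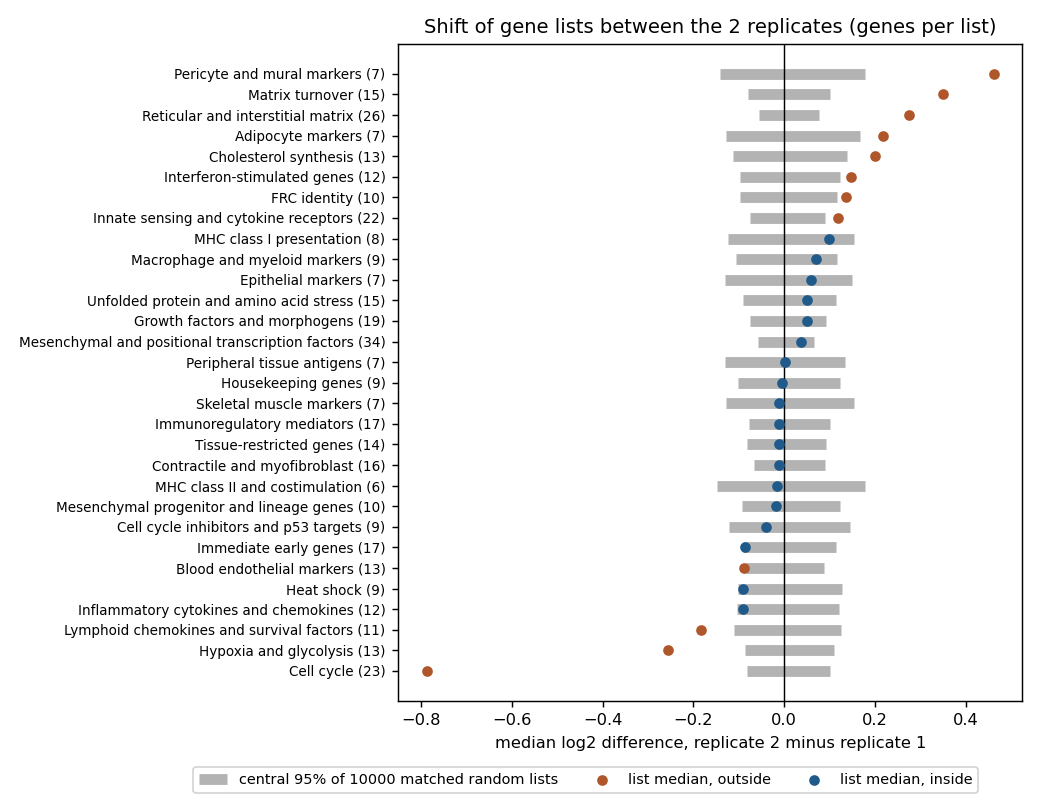
Median log2 difference (replicate 2 minus replicate 1) on the x axis for 30 gene lists on the y axis, with the number of genes in brackets, as points, and the central 95% of 10000 matched random lists as grey bars. The cell cycle median of -0.79 and the mural marker median of 0.46 lie farthest from 0.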

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

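The count of genes above the limit stayed within 1.5 times of 13300 under all 10 alternatives, between 9808 and 16536. Of the counts of list members under alternatives, 334 stayed within 1.5 times of the reported count and 56 did not, each under another limit. With the 99th percentile, the tissue-restricted genes and the median of all probe sets as the limit, in that order, the counts were 7, 6 and 6 for lymphoid factors (11 in the report), 3, 2 and 1 for peripheral tissue antigens (7), 1, 1 and 1 for complement (3), 3, 3 and 3 for adipocyte (7), 1, 0 and 0 for lymphatic endothelial (2), 1, 1 and 1 for blood endothelial (11), 2, 2 and 2 for myeloid (8), 0, 0 and 0 for T and NK cell (4), 0, 0 and 0 for B and plasma cell (2), 3, 2 and 2 for epithelial (7), 1, 1 and 1 for Schwann and neural (4), 4, 3 and 3 for skeletal muscle (7), 2, 1 and 1 for mesothelial markers (4) and 3, 2 and 1 for tissue-restricted genes (14). For MHC class II and costimulation (6), they were 3 and 3 with the last 2 limits. With vomeronasal receptors, counts were 17 for inflammatory cytokines (11), 7 for complement, 7 for lymphatic endothelial, 20 for myeloid, 7 for T and NK cell, 4 for B and plasma cell and 1 for erythroid markers (0), and 26 for tissue-restricted genes. With the 90th percentile they were 6 for complement, 5 for lymphatic endothelial, 13 for myeloid and 1 for erythroid markers. By construction a higher limit passes fewer genes, and signal over background is what limits these calls. Between the replicates, 648 genes differed at 1.5-fold. The correlation was 0.9924 with no filter, 0.9722 with the 99th percentile filter and 0.9825 with each probe set on its own. List medians that moved inside the range of random lists were the lymphoid factors with no filter (-0.0547) and with the highest probe set (-0.0547), interferon-stimulated genes with the 99th percentile filter (0.1040), and adipocyte (0.0174) and blood endothelial markers (-0.0659) with no filter. Medians that moved outside it were those of inflammatory cytokines with the 99th percentile filter (-0.1251) and immediate early genes with quantile normalisation (-0.1055), and that of tissue-restricted genes was 0.0319 with the 99th percentile filter. With the highest probe set, the lymphoid median could move only through Ccl19 (4 probe sets), since each other measured lymphoid gene has 1. The other filters left gene levels unchanged, so those medians could move only through members gained or lost. With no filter the lymphoid list gained Cxcl13 (0.059) and Il15 (0.46), both below the limit. The cause of the move with quantile normalisation was not tested. The matrix turnover median was 0.6578 with the 99th percentile filter. No list median that lay outside the random range turned its sign under the alternatives run. No paired analysis was possible because the series has 1 group.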

Other observations

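The tests of signal trend, of other cells diluting replicate 2, of leukocytes in replicate 1 and of the background limit were chosen only after the result was seen, and so was the division of the cell cycle list into parts. The tests of signal trend, diluting cells and the limit replaced earlier versions whose outcome was known, and the leukocyte test replaced one on pooled markers. The bootstrap resampled the genes of a list, all measured on the same 2 arrays. Its intervals show the spread between genes, not between cultures, and genes regulated together are not independent. A requirement that the bootstrap interval of the median exclude 0 left the tests on YAP, NF-kB and retinoic acid genes open. It was added after their values were seen. So was a requirement that most leukocyte or keratinocyte markers pass the tissue-restricted limit before their medians exclude anything.

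Genes named in this paragraph were chosen after their values were seen, and folds are against the olfactory receptor limit where an array lay below it, so those with an array below the tissue-restricted limit would be smaller against that one. Igf1 was 5.19-fold higher on replicate 2 and the binding protein genes Igfbp2 and Igfbp4 5.42-fold and 2.58-fold, while Igfbp3 and Igfbp5 differed 1.21-fold and 1.26-fold and Igf2 was 1.80-fold higher on replicate 1. Further genes of secreted factors higher on replicate 2 were Ccn3 (5.47-fold), the complement inhibitor Serping1 (5.15-fold), Wnt2 (3.47-fold), Vegfd (2.52-fold), Hgf (2.22-fold) and Bmp4 (2.18-fold), and the pericyte gene Rgs5 differed 5.81-fold. Lyz2 was at least 2.42-fold higher. On replicate 1, Il6 was 2.38-fold, Lif 2.13-fold and the integrin gene Itga4 2.41-fold higher. Some genes best known from other cells were well above both limits on both arrays, namely Cd53 (10.71 ± 0.06, SD, n = 2), Krt19 (10.83 ± 0.02) and Ncam1 (12.56 ± 0.09), while Ptprc and Epcam were below the limits. With the Y-linked genes on and Xist off, both samples have the pattern of male cells, a sex the labels do not give.

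Among genes of retinoic acid metabolism, the 3 retinaldehyde dehydrogenase genes were higher on replicate 2, Aldh1a2 3.90-fold, Aldh1a1 3.38-fold and Aldh1a3 3.02-fold, together with Dhrs3 (3.43-fold), all chosen after their values were seen. Rdh10, which oxidises retinol, had a difference of -0.0021 (log2, replicate 2 minus replicate 1). A retinoic acid response in replicate 2 may go with this. Its response genes had a median difference of 0.1930, above the 0.1369 that bounds the random lists, but 5 of 9 were higher and 4 lower, and the bootstrap interval ran from -0.23 to 0.51, so the response stays open.

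Cell cycle genes were lower and matrix genes higher on replicate 2. Within the fixed list, the G2 and mitosis genes (16 genes, median -0.86) moved more than the replication genes (7 genes, -0.43), and 18 further cell cycle genes had a median of -0.7603, with 18 of 18 lower, the least of them the replication genes Cdc6 (-0.076), Cdt1 (-0.28) and Uhrf1 (-0.37), named after their values were seen. A trend of the difference with signal in the deposited values, already normalised by RMA, is argued against, since the fitted trend was at most 0.0277 in size. Leukocytes, endothelial or epithelial cells diluting replicate 2 would lower fibroblast genes alike. The lowest median of the identity, matrix and contractile lists was -0.0125, that of the contractile genes (bootstrap interval -0.073 to 0.056). Higher matrix genes are part of the pattern and these medians were known beforehand, so the test could not have favoured dilution. The contractile genes did not fall with the cell cycle genes, but their median was known beforehand as well. It therefore excludes nothing, and dilution stays open. Over all measured members, list medians for such other cells ran from -0.0659 (blood endothelial) to 0.0519 (macrophage and myeloid). Most of these markers did not pass the tissue-restricted limit, so these medians decide nothing either. A denser replicate 2 culture with lower YAP activity stays open. YAP target genes were at -0.0912, below the -0.075 that bounds the random lists as the prediction required. Their bootstrap interval ran from -0.15 to 0.012, and 12 of 17 genes were lower. Ccn1 (-0.034) and Ccn2 (-0.023) were not among them, because the YAP list held no gene of the fixed lists. More mural cells in replicate 2 and a difference in culture time within the stated 7 to 10 days also stay open and were not tested, and the design, with 1 group, names no biological difference to set against these.

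Il1a, Cxcl5 and Ppbp were higher on replicate 1, and each explanation tested stays open. The lowest of the 3 leukocyte list medians was -0.0504, but 38 of the 40 leukocyte markers were not above the tissue-restricted limit, so a small admixture would not be seen. Keratinocytes, another source of Il1a, had a median of -0.0276 over 18 genes (bootstrap interval -0.10 to 0.087), which met the prediction written against them, but 15 of the 18 were not above that limit, so this excludes nothing. Single genes, named after their values were seen, went both ways. Pkp1 (-0.68), Perp (-0.68), Lce1h (-1.83) and Lce1i (-1.53) were higher on replicate 1 and Ivl (0.45) on replicate 2. Of these, only Pkp1 and Lce1h passed the tissue-restricted limit on both arrays, and Ivl and Perp passed it on neither. For stronger NF-kB activity in replicate 1, target genes had a median of -0.1691, below the -0.10 that bounds the random lists as the prediction required, with 10 of 14 lower on replicate 2, but the bootstrap interval ran from -0.38 to 0.012.

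Markers of endothelial cells and lymphocytes passed the olfactory receptor limit in 19 of 43 cases. A limit below the signal of silent probe sets is a candidate explanation. The pooled share of these markers, 44.19%, was close to the 40% of tissue-restricted genes. It mixes unlike lists, with 22.2% for lymphatic endothelial, 40% for T and NK cell, 25% for B and plasma cell and 68.75% for blood endothelial markers. For blood endothelial markers the pooled share therefore decides nothing. They passed the olfactory receptor limit in 11 of 16 cases and the stricter limit in 1 of 16. Of the tissue-restricted genes, 2 of 35 passed the stricter limit, and no test compared these shares. A small admixture of such cells stays open.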
